A study of Mus musculus with 63 samples.

How the data were processed

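Single cells were sorted by surface markers, their polyA RNA was amplified with a whole-transcriptome kit and libraries were made with a transposase kit, per the labels' protocols. The deposited table gives TPM per gene symbol and library, made by the authors. HISAT2 2.1.0, SAMtools 0.1.19, StringTie 1.3.4, bcl2fastq 2.16.0.10 and the build mm10 are named in the submitters' processing notes, with no role or order. TPM has the same sum in each library and keeps no depth, so neither counts nor count tests were used, and the precision of a low value cannot be given. The table held 23420 rows and 63 libraries, and each column matched 1 sample title.

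Calculations used Python 3.11.15, NumPy 2.4.6, pandas 2.3.3 and SciPy 1.17.1, with figures drawn in matplotlib 3.10.9. In 27 rows the symbol had turned into a calendar date, and 2 such symbols occurred again, so these rows were left out of gene values. They held at most 0.540% of the TPM of a library. Symbols of 2 list members were matched through synonyms in a RefSeq gene table, and 21 members had no row, among them the 13 mitochondrially encoded genes. Gene coordinates are from GENCODE M21 on GRCm38, the assembly that mm10 names.

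Libraries of the same iR9 cell number with suffixes 2 and 3 were averaged if each was the other's best match and their Pearson r of log2(TPM + 1), over genes at TPM of at least 1 in at least 10% of libraries, was above that of every different-number pair. All 15 pairs met this. Gene values are means of log2(TPM + 1) over cells, so a difference understates the change of low genes. Lists used 7421 genes at TPM of at least 1 in at least 10% of the 48 cells. A list's median difference was placed among those of 10000 random lists of the same size, drawn from 20 expression bins, and stands apart outside their central 95%. Of 30 lists, 26 had at least 3 measured members. The B cell, pluripotency and sort-negative lists had 1 each, and the mitochondrial list had 0. Shares of cells have exact Clopper-Pearson 95% intervals, which cover counting error only. A cell was said to hold markers of a list with at least 3 members at TPM of at least 10. The sort gave single cells and no doublet caller was run. All 48 cells had more than 1000 genes and none was removed.

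Named genes were fixed by rule before the data were examined. They were the ILC progenitor and sort gate lists with Runx1 and Hoxa9, up to 4 members with the largest differences in each other list, and the 12 largest differences in each direction among genes at TPM of at least 1 in at least 50% of the higher group's cells, with the same sign for iR9 libraries of each suffix. Predicted and pseudogene symbols were left out. Of the ILC progenitor list, 1 member and its co-detection with other factors are not reported here, while the list values include it. The group of 1 sample each allowed no test, standard error or count of changed genes.

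The functions were tested on simulated data of 7421 genes, in which each gene's values were redrawn over all cells and 200 genes at or above the median level were raised. A positive difference was found for 63.6% of genes raised 2-fold, 88.3% of those raised 4-fold and 87.8% of those raised 8-fold. With 2000 random lists each, of 200 unchanged lists of 12 genes 5.0% lay outside the percentiles, and of 50 lists raised 8-fold, 90.0% did. Unchanged lists were drawn from the same genes as the random ones, so a share near 5.0% follows from the procedure. Each gene was redrawn on its own, which removed correlation between genes. The simulation therefore gives no rate at which real, co-expressed lists stand apart. Alternatives covered the counting of same-number libraries, each suffix alone, cells with similar numbers of genes, thresholds, pseudocounts, scaling, gene filters and the ratio of mean TPM. Chosen after seeing the data were leaving out cells with at least 3 myeloid or mast cell markers, leaving out each cell in turn, detection at TPM of at least 10 and setting TPM below 10 to 0.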

Results

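Common helper innate lymphoid progenitors (CHILPs) are bone marrow cells that give rise to the helper innate lymphoid cells (ILCs), the lymphocytes of groups ILC1, ILC2 and ILC3, which lack rearranged antigen receptors. The series held polyA RNA profiles of single mouse cells of this phenotype from 2 sources. One group was wild-type CHILPs (WT), with 29 libraries. The other was cells of the same surface phenotype that carried a GFP mark (iR9), with 34 libraries. They were derived from pluripotent stem cells, per the series title, and sorted from the marrow of recipient mice lacking Rag2 and Il2rg 4 weeks after transplantation. The comparison asks how far the regenerated progenitors resemble their natural counterparts. Values were TPM, transcript abundance scaled to the same total in each library, for 23420 gene symbols, so the read depth of each library is unknown. No animal or culture was named in the labels, which makes each group 1 sample of many cells. The differences below are therefore descriptions with their spread over cells, and no test between groups was made.

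The iR9 titles ended in 1 (3 libraries), 2 (15 libraries) or 3 (16 libraries), while every WT title ended in 1. For 15 cell numbers, libraries with the suffixes 2 and 3 both existed. Their Pearson r across genes lay between 0.974 and 0.992 for the 15 same-number pairs and was at most 0.410 for the 225 different-number pairs. Each library was the best match of its same-number partner. By a rule set before the data were examined, each such pair was counted as 1 cell with the mean TPM. The 34 iR9 libraries, stated in the series design as 34 cells, thus counted as 19 cells, of which 3 had suffix 1.

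WT cells had a median of 2938 genes at TPM of at least 1, with a range of 1189 to 5939 over 29 cells. The iR9 cells had a median of 1732, with a range of 1514 to 3238 over 19 cells. The 3 iR9 cells of suffix 1 had a median of 3033, and the 16 others one of 1685. At TPM of at least 10 the medians were 2495 in WT and 1346 in iR9 cells, so counts of cells at that level favour WT for many genes. At TPM above 0 they were 3662 and 3473. There each of the 15 averaged pairs counts a gene found in either library, unlike a WT cell. Transcripts of widely used genes were also listed at 0 in some cells, Gapdh in 5 and Hprt in 8 of 48, so a value of 0 here means only that a gene is listed at 0.

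**Figure D1:**
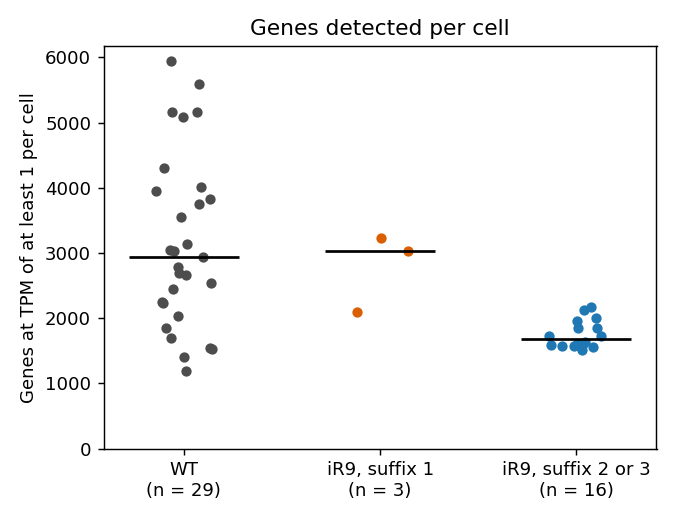
Number of genes at TPM of at least 1 (vertical axis) in each cell, for WT cells and for iR9 cells by title suffix. Points are cells and lines are medians, which lie at 2938 for WT, 3033 for iR9 suffix 1 and 1685 for the other iR9 cells.

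The mean profiles of the groups correlated across genes with a Pearson r of 0.829 and a Spearman rho of 0.640 over 7421 genes, which are not independent replicates. At 9 cells per profile, 100 random draws of WT against WT cells gave a median r of 0.807 (range 0.778 to 0.830). Draws of iR9 against iR9 cells gave 0.839 (0.825 to 0.851). Draws of WT against iR9 cells gave 0.741 (0.705 to 0.773), below every draw within a group. The groups also differed in title suffix and in genes detected, and most iR9 cells were averages of paired libraries. The lower r can therefore not be assigned to the source of the cells.

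Transcription factors and receptors of ILC progenitors were mostly lower in iR9 cells. Of the 16 members measured, 13 had a lower mean and 3 a higher one, and the median difference in log2(TPM + 1), iR9 minus WT, was -2.43. The median difference over all genes was -0.88, so each list was placed among 10000 random lists matched on expression. This list lay below all of them (percentile 0). Tcf7, encoding the factor TCF-1 of early lymphoid commitment (GRCm38 chromosome 11, 52252371 to 52283014), had a mean of 7.55 ± 3.83 (SD over 29 cells) in WT and 2.76 ± 3.56 (SD over 19 cells) in iR9 cells. At the planned threshold, TPM of at least 1, it was in 28 of 29 WT cells (96.6%, exact binomial 95% interval 82.2 to 99.9%) and 10 of 19 iR9 cells (52.6%, 28.9 to 75.6%). At TPM of at least 10, a threshold chosen after seeing the data and used for the gene counts below unless stated, it was in 22 of 29 WT cells (75.9%, 56.5 to 89.7%) and in 5 of 19 iR9 cells (26.3%, 9.15 to 51.2%). These intervals cover counting error only. Tox, a factor needed for ILC development (chromosome 4, 6686353 to 6991557), reached that level in 20 WT cells and 1 iR9 cell, and TPM of at least 1 in 21 and 2, with a difference of -5.06. Gata3, required in ILC2 and in progenitors (chromosome 2, 9857078 to 9890034), did so in 24 WT and 8 iR9 cells, with a difference of -4.11. Zbtb16, encoding PLZF, a factor of ILC precursors (chromosome 9, 48654297 to 48836222), reached it in 12 WT cells and was listed at 0 in all 19 iR9 cells. Bcl11b was likewise at 0 in the iR9 cells and at TPM of at least 10 in 8 WT cells. Pdcd1, Rora and Ets1 differed by -3.35, -3.02 and -2.62.

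Id2 and Cxcr6 went the other way within the same list. Id2, an inhibitor of E proteins that marks the ILC lineage (chromosome 12, 25093799 to 25097140), was at TPM of at least 10 in every cell of both groups, with means of 12.85 ± 0.87 in iR9 and 11.21 ± 2.80 in WT cells. The lowest values were 15.65, 26.31, 63.55 and 216.2 TPM in WT cells 5-1, 16-1, 6-1 and 29-1. These cells held Dntt, a gene of the common lymphoid progenitor list, at 1121 to 2137 TPM. Cxcr6, a chemokine receptor (chromosome 9, 123806475 to 123811760), was at TPM of at least 10 in 17 of 19 iR9 and 9 of 29 WT cells, with a difference of 4.68. At the planned TPM of at least 1 it was in 19 iR9 and 27 WT cells. The WT cells between these levels held only 1.05 to 7.74 TPM. Reads crossing between libraries are not excluded for such low values, so the WT count depends on the threshold.

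ILC3 and lymphoid tissue inducer (LTi) genes were higher in iR9 cells. Of 12 members measured, 8 had a higher and 4 a lower mean, and the median difference of 0.81 lay above all 10000 matched random lists (percentile 100). Ltb, encoding lymphotoxin beta (chromosome 17, 35194439 to 35196320), averaged 11.52 ± 2.23 in iR9 and 7.64 ± 4.04 in WT cells. Lta differed by 2.66. Il23r, the receptor of interleukin 23, was at TPM of at least 10 in 6 of 19 iR9 cells (31.6%, 12.6 to 56.6%) and in 0 of 29 WT cells (0 to 11.9%), and at TPM of at least 1 in 7 and 3. Il22 reached TPM of at least 10 in 3 iR9 cells and no WT cell, and TPM of at least 1 in 10 and 1. Its mean TPM of 678 in iR9 cells therefore rests on few cells. The iR9 cells between these levels held only 1.48 to 7.31 TPM and had suffix 2 or 3, as the 3 high cells did. Reads crossing between libraries are not excluded for such low values. At least 3 members of this list reached TPM of at least 10 in 12 iR9 cells (63.2%, 38.4 to 83.7%) and 10 WT cells (34.5%, 17.9 to 54.3%).

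The title suffix and the group can hardly be told apart, since all WT cells and only 3 iR9 cells had suffix 1. With these 3 cells alone, the ILC progenitor list had a percentile of 2.01 and the ILC3 and LTi list one of 99.96, while the differences of Tcf7, Tox and Gata3 shrank to -2.22, -2.35 and -0.85. Among the suffix 1 cells with fewer than 3 myeloid or mast cell markers, 14-1 and 17-1, the Tcf7 difference was -0.12, that of Tox -1.36 and that of Gata3 -1.29. The lower Tcf7 mean thus rests on the iR9 cells of the other suffixes and on the suffix 1 cell 12-1, at 1.22 TPM. In cells 14-1 and 17-1 the direction turned for Rora (2.70), Ets1 (1.36), Tox2 (0.36) and Il22 (-0.045), while Cxcr6 (4.91) and Ltb (4.39) stayed higher.

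**Figure D2:**
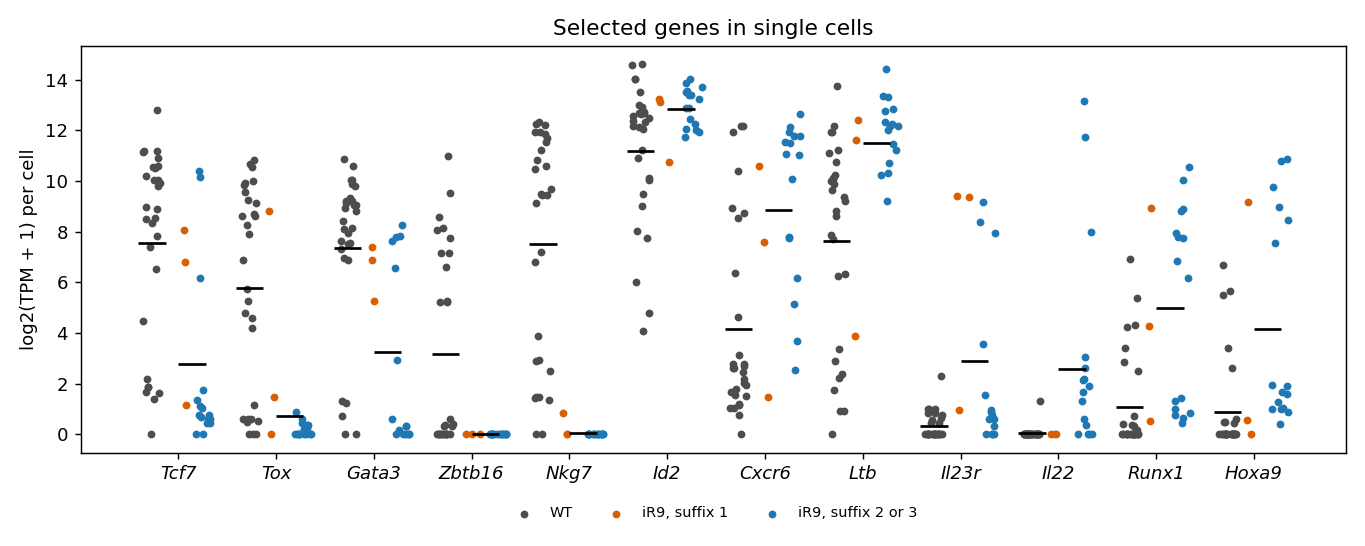
Expression of 12 genes as log2(TPM + 1) (vertical axis) in each cell, with WT cells in grey, iR9 cells of suffix 1 in orange and other iR9 cells in blue. Lines are means per group, for example 7.55 in WT and 2.76 in iR9 cells for Tcf7, and 7.64 and 11.52 for Ltb.

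Genes of the other ILC fates and of earlier lymphoid stages were lower or close to the matched lists. For ILC1 and natural killer cells, 7 of 8 measured members had a lower mean, with the list at percentile 4.97. Nkg7, a cytotoxic granule protein (chromosome 7, 43437073 to 43438249), was at TPM of at least 10 in 20 of 29 WT cells and 0 of 19 iR9 cells, and its difference of -7.47 was the lowest among the named genes. At least 3 members reached TPM of at least 10 in 16 WT cells and 1 iR9 cell, a count favoured by the larger number of genes at that level in WT cells. For ILC2 genes, 7 of 8 were lower, at percentile 25.7, and 18 WT cells and 3 iR9 cells held at least 3 members at TPM of at least 10. This count is favoured in WT cells in the same way. Gata3, Rora and Bcl11b are also members of the ILC progenitor list, so the count is not separate from that result. Il17rb, a receptor of interleukin 25, was listed at 0 in the iR9 cells and at TPM of at least 10 in 9 WT cells. All 8 measured genes of common lymphoid progenitors had a lower mean, at percentile 0.2. Among them Ly6d was at 0 in the iR9 cells and at TPM of at least 10 in 7 WT cells. WT cells 5-1, 16-1 and 29-1 held 47378.4, 19773.8 and 10269.3 TPM. The other WT cells of this count held only 11.37 to 63.27 TPM, for which reads crossing between libraries are not excluded.

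At the planned TPM of at least 1, Tox and Tcf7 were both in 20 WT cells (69.0%, 49.2 to 84.7%) and 2 iR9 cells (10.53%, 1.301 to 33.1%), and Id2 and Tcf7 in 28 WT cells (96.6%) and 10 iR9 cells (52.6%). The 2 iR9 cells with Tox and Tcf7 were 14-1 and 12-1, both of suffix 1. Cell 12-1, which had mast cell markers, held only 1.22 TPM of Tcf7 and 1.74 TPM of Tox. Tox and Tcf7 were both at TPM of at least 10 in 18 WT cells (62.1%, 42.3 to 79.3%) and 1 iR9 cell (5.26%, 0.133 to 26.03%). Zbtb16 and Pdcd1 were both at that level in 10 WT cells and in 0 of 19 iR9 cells (0 to 17.6%).

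Genes of the sort gate gave a mixed picture. Of the 6 genes on which cells were included or that mark the population, 5 had a lower mean, with the list at percentile 83.3. Il7r, encoding CD127, was at TPM of at least 10 in 16 iR9 and 25 WT cells. Itga4, encoding the α4 chain, was lower by a difference of -2.96 and at that level in 5 of 19 iR9 and 19 of 29 WT cells. Flt3, encoding CD135, on which cells were excluded, was at 0 in the iR9 cells and at TPM of at least 10 in 3 WT cells. Il2ra, encoding CD25, was under TPM of 1 in all cells. Ly6a, encoding Sca1, had a mean higher by 3.22 in iR9 cells. Runx1 (chromosome 16, 92601466 to 92826149) and Hoxa9 (chromosome 6, 52223100 to 52231089) were higher by 3.91 and 3.26 in iR9 cells. Runx1 was at TPM of at least 10 in 11 of 19 iR9 and 4 of 29 WT cells, and Hoxa9 in 7 and 3. In the iR9 cells 14-1 and 17-1 of suffix 1 the Runx1 difference was 1.304 and that of Hoxa9 turned to -0.62.

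Among the other lists fixed beforehand, erythroid genes were higher, with 4 of 4 measured members up in mean and a percentile of 99.99. Hba-a2, an alpha globin, was at TPM of at least 10 in 15 iR9 and 2 WT cells. The higher means were absent in the iR9 cells 14-1 and 17-1, with Hba-a2 at 0.19, Hba-a1 at -0.04 and Car2 at -1.42. Cell cycle genes were lower (15 of 15, percentile 0.795), as were ribosomal protein genes (23 of 23, percentile 0.135). At least 3 cell cycle genes were at TPM of at least 10 in 10 WT cells and 1 iR9 cell. WT cells 6-1, 8-1 and 29-1 held 20, 16 and 15 of the 20 listed, and 5-1 and 23-1 held 10 each. The other WT cells of this count held 3 to 5, so much of the WT signal lay in few cells. Of these, 5-1, 6-1 and 29-1 are among the WT cells with low Id2 and high Dntt. Both cell cycle and MHC class I lists left the outer percentiles among cells with similar numbers of genes. MHC class I and antigen processing genes had a percentile of 99.7 with 6 of 11 members higher. Multipotent progenitor genes, at 97.6 with a median difference of -0.11, lay within the central 95% of random lists under most alternatives. Of this list 3 members were higher and 3 lower, Cd27 by a difference of -4.29, and at least 3 reached TPM of at least 10 in 12 WT cells and 1 iR9 cell.

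**Figure D3:**
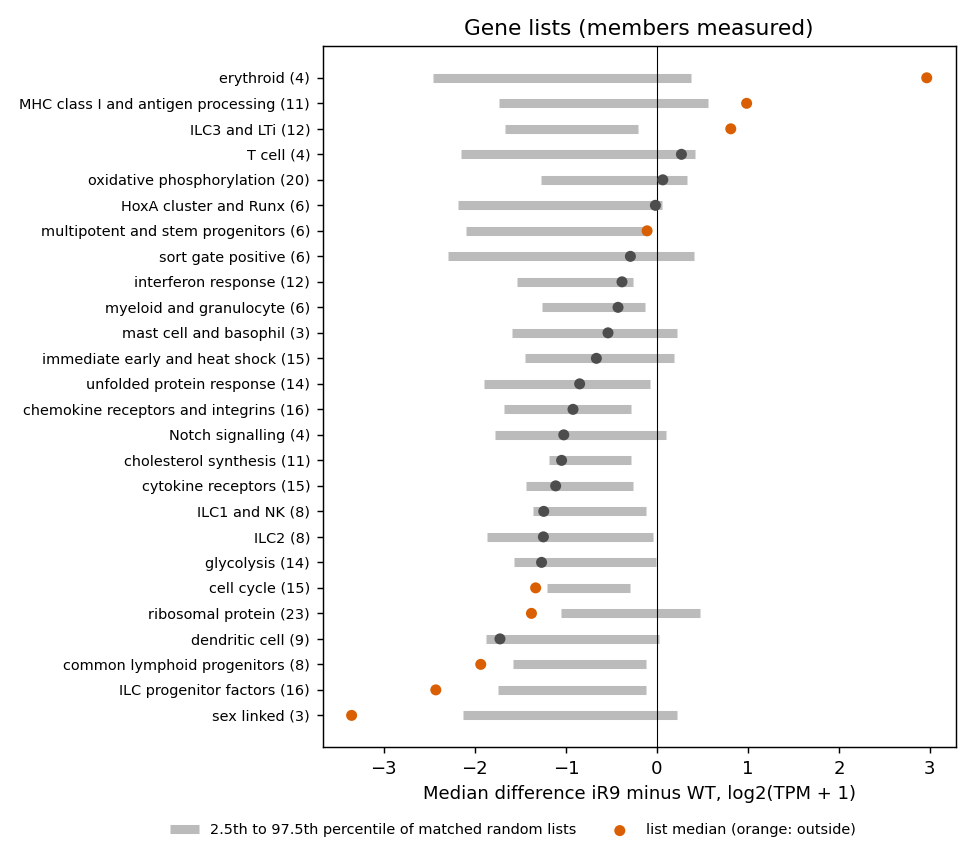
Median over list members of the difference in mean log2(TPM + 1), iR9 minus WT (horizontal axis), for 26 gene lists, with grey bars for the central 95% of 10000 matched random lists. Orange points lie outside their bar, such as ILC progenitor factors at -2.43 and ILC3 and LTi genes at 0.81.

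The genes with the largest higher means, chosen by a fixed rule, included Upp1 (difference 6.37), Rgcc (5.33), Gpr183 (5.18), Serinc2 (5.06), Klrb1b (4.52) and Cd82 (4.30). Gpr183, an oxysterol receptor that guides lymphoid cells, was at TPM of at least 10 in 15 of 19 iR9 and 7 of 29 WT cells. The largest lower means included Tyrobp (-5.99), Plac8 (-5.86), Stmn1 (-5.74), Npm1 (-5.66), H2-Ab1 (-5.49), Crip1 (-5.35) and Cdk4 (-5.22). With the iR9 libraries of suffix 1 alone, Tyrobp differed by -0.54, Npm1 by -2.62 and Plac8 by -3.22. These libraries include cell 12-1, which had mast cell markers. By the rule, the other genes named with them were lower there too.

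Cells with transcripts of another lineage were present in both groups. The iR9 cell 12-1 held 8 of 10 listed mast cell and basophil genes, with Tpsb2 at 106594.6 TPM and Cpa3 at 65135.7 TPM. The WT cells 21-1 and 26-1 held 5 myeloid genes each, with Lyz2 at 35870.9 and 126914.2 TPM, and 9 and 8 of 13 listed dendritic cell genes, with Cd74 at 83286.2 and 74392.7 TPM. Dendritic cell markers were not confined to them, with at least 3 in 23 WT cells (79.3%, 60.3 to 92.0%) and 4 iR9 cells (21.1%, 6.05 to 45.6%). Some of these WT cells held only low values of genes that 21-1 and 26-1 held at very high levels. In WT cell 28-1, for example, Cd74 was at 20.75 TPM and H2-Ab1 at 12.24 TPM. Reads crossing between libraries are not excluded for such values, and with markers at TPM of at least 50 the WT share was 51.7%. WT cell 5-1 held 8, with Siglech at 1704 TPM. Without iR9 cell 12-1 and WT cells 21-1 and 26-1 the ILC progenitor list stayed at percentile 0 and the ILC3 and LTi list at 100.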

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

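Leaving out cells with at least 3 myeloid or mast cell markers or each cell in turn, detection at TPM of at least 10 and setting TPM below 10 to 0 were chosen after seeing the data. No paired analysis was possible because the results come from no test. Values named below changed sign, moved by over 1 SD (over cells, draws or pairs) or left the 95% binomial interval of a share. List values here are the list median minus that of matched random lists. The ILC progenitor and the ILC3 and LTi lists stayed outside the percentiles in each setting with all its cells, as did the erythroid list, but the ILC progenitor list reached 2.62 with TPM below 10 set to 0 and 1 cell left out, and had 6.08 for cell 17-1 alone against WT. The sex-linked list did where it had 3 measured members. Common lymphoid progenitor and ribosomal protein genes lost that without a gene filter, and cell cycle genes with suffix 1 or 2 alone and in the shared range of 1561 to 3053 genes. MHC class I genes lost it with suffix 1, in the shared range, under quantile normalization and for the ratio of mean TPM. Leaving out each cell in turn kept the ILC progenitor list at or under percentile 0.08 and the ILC3 list at or over 99.99, but took the cell cycle list to 4.94. Lists inside the percentiles at first left them under some settings, ILC1 and natural killer genes (percentile 4.97) among them, at 2.48 with suffix 1, 2.14 with a pseudocount of 10, 0.27 after quantile normalization, 0.71 without a gene filter and 0 for the ratio. ILC2 genes did so in the shared range (1.14) and for the ratio (0.01). Dendritic cell genes (4.90) were low in the shared range (0), with TPM below 10 set to 0 (0.625), after quantile normalization (0.89), with genes in 30% of cells (0.305) and for the ratio (0). Without the cells with myeloid or mast cell markers they lay at 40.75, and with 1 cell left out at up to 19.7. HoxA cluster and Runx genes (96.9) were high with TPM below 10 set to 0 (99.1), a pseudocount of 10 (97.9), no ribosomal protein genes (97.8), genes in 30% of cells (99.5) and the ratio (98.96). The median difference of all genes was -0.88, and -0.19 after quantile normalization, -0.43 with a pseudocount of 10 and -1.26 with 0.1. TPM keeps no depth, which limits every low value.

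For the iR9 libraries of suffix 2 alone the profile r was 0.805. For the 3 of suffix 1 the profile r was 0.673, the median of genes detected 3033, and differences reversed for Rora (0.35), Il22 (-0.045), Lyz2 (6.55), Cpa3 (3.60), Tapbp (0.39), Tap1 (1.19), Pgk1 (1.71), Sc5d (0.66), Pdia3 (1.56), Ddit3 (0.77) and Pdia4 (1.64). The reversal of Cpa3 rests on cell 12-1 with mast cell markers, at 65135.7 TPM against 9.49 in 14-1 and 0 in 17-1. Without 12-1 the Rora difference was 2.70. List values there moved for myeloid (2.29), erythroid (1.65), mast cell (3.25), immediate early (-1.73) and oxidative phosphorylation genes (-1.83). Of these 3 cells only 12-1 held at least 3 mast cell, myeloid or erythroid markers. Quantile normalization reversed Runx3 (0.22) and Pdia4 (0.83), and the ratio of mean TPM reversed Cpa3 (3.01), Pdia4 (0.056) and the multipotent list (-1.25), which was -0.071 with genes in 30% of cells. The ratio moved the lists of ILC1 (-4.11), ILC2 (-2.17), common lymphoid progenitors (-2.77), myeloid (-2.08), mast cell (3.35), dendritic cell (-3.23), cell cycle (-3.47), Notch (1.27), cytokine receptor (-2.20) and sex-linked genes (-4.84). Without a filter the erythroid value was 0.0072 and the sex-linked one -0.47, and with genes in 30% of cells interferon genes had 2.68. The profile r was 0.810 in the shared range and without ribosomal protein genes, 0.874 without a filter, 0.773 with genes in 30% of cells and 0.620 for the ratio. With Spearman rho the lowest same-number value was 0.665 and the highest different-number value 0.487; genes in 30% of libraries gave 0.375 for the latter. All 15 pairs were still merged.

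Among iR9 cells, markers of multipotent, myeloid, mast cell and cell cycle lists and Tox with Tcf7 were in 0% with suffix 2 or 3 alone, and common lymphoid markers in 0% with suffix 2. With suffix 1, ILC1, common lymphoid and T cell markers were in 0%, multipotent, myeloid, mast cell and cell cycle markers in 33.3%, ILC2 and dendritic cell markers and Tox with Tcf7 in 66.7%, and Id2 with Tcf7 in 100%. Cell 12-1 gave the multipotent, myeloid and mast cell markers there and was counted for Tox with Tcf7 and Id2 with Tcf7. In the shared range, erythroid markers and Gata3 with Tbx21 were in 0% of WT cells, cell cycle markers in 0% of iR9 cells, Id2 with Tcf7 in 100% and Zbtb16 with Tcf7 in 23.1% of WT cells. Without the cells with myeloid or mast cell markers, myeloid markers were in 0% of both groups, and multipotent and mast cell markers in 0% of iR9 cells. At TPM above 0 the iR9 median was 3473 genes, Tox with Tcf7 were in 86.2% of WT cells, and Id2 with Tcf7 in 89.5% and Tox with Tcf7 in 42.1% of iR9 cells. At TPM of at least 5 or 10, Id2 with Tcf7 were in 75.9% of WT and 26.3% of iR9 cells. With markers at TPM of at least 1, ILC1 (82.8%), ILC2, ILC3 and common lymphoid (86.2% each), dendritic cell (100%) and cell cycle markers (55.2%) moved in WT cells, and ILC2 (52.6%), ILC3 (100%), erythroid (73.7%) and dendritic cell markers (89.5%) in iR9 cells. At 50, multipotent (20.7%), common lymphoid (31.03%) and dendritic cell markers (51.7%) moved in WT cells and common lymphoid markers (0%) in iR9 cells.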

Other observations

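The tests of the title suffix, of low values that follow it and of Runx1 with Hoxa9 were chosen after the result was seen. Ddx3y and Eif2s3y, on the Y chromosome, were at TPM of at least 10 in 13 and 12 of 29 WT cells and in 0 of 19 iR9 cells, and the sex-linked list lay at percentile 0.025. Xist, a member of the same list, was at TPM of at least 1 in 0 cells of either group, so the values do not give the sex of the iR9 cells. Hes1, a target of Notch signalling, was at TPM of at least 10 in 17 WT cells and 1 iR9 cell. Immediate early genes went both ways, with Junb higher by 3.68, Ier2 higher by 3.21 and Fos at -2.29 in iR9 cells. The dendritic cell list lay inside the percentiles at 4.90, under 2.5 in 5 alternatives, but at 40.75 without the cells with myeloid or mast cell markers. Of its members, H2-Aa differed by -3.99 and H2-Eb1 by -3.69, and H2-Aa by 0.19 in the iR9 cells 14-1 and 17-1 alone. S100a8 was at TPM of at least 10 in 3 iR9 cells and listed at 0 in the WT cells.

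Lists inside the percentiles, some of which left them under alternatives, were T cell (96.1), HoxA cluster and Runx (96.9), interferon response (94.95), oxidative phosphorylation (90.4), myeloid (86.2), mast cell (71.5), unfolded protein response (64.6), chemokine receptors and integrins (55.5), immediate early (52.1), Notch (33.4), cytokine receptors (17.3), glycolysis (14.03), cholesterol synthesis (8.79) and dendritic cell genes (4.90).

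The lower ILC progenitor factors and higher ILC3 and LTi genes of iR9 cells may be cellular, or may come from technical differences. Among cells in the shared range of genes detected, the percentiles stayed at 0.05 and 99.48, which argues against fewer genes detected as the whole cause, although the WT median there (2538) was still above the iR9 one (1732). Without the 3 cells with myeloid or mast cell markers they stayed at 0 and 100, which argues against these cells as the cause, while cells with erythroid or dendritic cell markers were not left out. With TPM below 10 set to 0, the ILC3 list stayed at 100, which argues against crossing reads below that level as its cause. The progenitor list had 1.24 and reached 2.62 when 1 cell was left out. This setting keeps crossing reads that reach TPM of at least 10, so reads crossing between libraries stay open for both lists. The library set given by the suffix cannot be told apart from the group, since only 2 suffix 1 iR9 cells had fewer than 3 myeloid or mast cell markers, with percentiles of 2.29 and 6.08 for the progenitor list and 100 and 99.08 for the ILC3 list.

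Low values of genes that another cell holds at a very high level were seen, and may come from reads crossing between libraries of one suffix. For 8 genes peaking at 5000 TPM or more in WT cells and under 100 TPM in the iR9 cells, a value above 0 was listed in 29.2% of cases in iR9 cells of suffix 1 (12.6 to 51.1%) and in 19.5% in the others (13.1 to 27.5%). The intervals overlap, so the test did not separate the suffixes. Its cases share genes and cells, which the intervals ignore, and genes peaking in iR9 cells of suffix 1 were not covered. Tpsb2, at 106594.6 TPM in iR9 cell 12-1, was at 17.44 TPM in iR9 cell 14-1. It was at 15.22, 27.33 and 30.84 TPM in WT cells 12-1, 4-1 and 28-1, all of suffix 1. In all other cells, of every suffix, it was listed at 0. Crossing within suffix 1 was not tested for this gene and stays a candidate explanation. For the reverse, only Il22 qualified, at 0% in suffix 1 (0 to 70.8%) and 69.2% in the other iR9 cells (38.6 to 90.9%). This 1 gene is too few to weigh the number of genes detected. No biological explanation was tested.

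Runx1 and Hoxa9 were found in the same iR9 cells, and 1 transcript carrying both genes is a candidate explanation. Of the 7 iR9 cells with Hoxa9 at TPM of at least 10, 100% also held Runx1, against 1 of 3 WT cells. Another 4 iR9 cells held Runx1 without Hoxa9, which keeps this open, as does expression of both genes from their own loci.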
